A study of Drosophila melanogaster and Drosophila simulans and Drosophila yakuba with 72 samples.

How the data were processed

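MicroRNA (miRNA) was measured on 36 arrays that each carried 2 labelled samples, 72 samples in all. Per the labels, the samples were whole animals of 6 strains: Oregon-R, Canton-S, Samarkand and Zimbabwe-109 of Drosophila melanogaster, and a stock each of D. simulans and D. yakuba. The labels give 2 stages. The later is marked PF, read here as puparium formation, the onset of metamorphosis. The earlier is marked as at least 18 before it, read here as hours. It is called the earlier stage. Males were sampled in all 6 strains and females in Oregon-R, Zimbabwe-109 and D. simulans, which makes 18 groups of 4 samples. The series' design text calls the 4 samples of a group biological replicates, and per the labels RNA was isolated from pools of animals.

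Per the file headers, the deposited scanner files hold an intensity for each spot, the median pixel density on a linear scale, with the sample and dye of each channel named. The labelling and hybridization were done by a service company, per the labels' protocols; the scanner and its software are not given in the sources used here. The files list no local background, so the 689 empty spots of each array served in its place, and their medians ranged from 49.1 to 136 in Cy3 and from 29.8 to 64.6 in Cy5. A second table deposited by the authors holds a processed intensity for 4333 of the 5022 spots, the 689 empty spots being left out of it. Its values are linear and lie above 0, the smallest at 8.78e-05. Set against the scanner values of the same channel, its columns had rank correlations of at least 0.805, with a median of 0.948. Bright spots differed from the scanner values less the empty spots by a factor per channel of -1.12 to 0.82 on the log2 scale. The column medians ran from 0.00375 to 5.04. How that table was scaled and centred is not given in the sources used here, and it served only as an alternative.

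Each array held the 2 stages of the same strain, sex and replicate number in opposite dyes, as the file headers show, and the dyes were swapped in 2 of the 4 arrays of every group pair. The array was therefore known to pair samples and entered the reported fit as a block. Deviations from the group means of the 2 samples on an array correlated at 0.0123 to 0.637, above 0.1 on 31 of 36 arrays, and the paired fit estimated a correlation of 0.411 within arrays. The 36 arrays lay on 7 slides, of which 5 held males, 2 held females and 0 held both. Median correlations between replicates of a group ranged from 0.895 to 0.992.

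Intensities were corrected with limma's normexp method with an offset of 50 on the empty-spot background, normalized within arrays by loess, and made comparable between arrays by quantile normalization of the average intensities (Aquantile). The median of the 3 spots of a probe was taken on the log2 scale. A probe was called detected in a sample when its median intensity exceeded the median of the empty spots by 3 SD. Probes detected in at least 3 samples of some group were tested, 272 of 1339 probes, for 166 distinct miRNA arms or sequences. Of these, 90 were listed for D. melanogaster and 60 were detected in all 72 samples. The 1339 probes include 92 custom probes, which were tested by the same rule. The array also held 8 probes for 2S rRNA, which were left out of the tests. Probes carry the names of the array's design; a probe listed for several species is given here under its D. melanogaster name where it has one. The prefix of 2 custom probes, given here as 53-3p and 153-5p, is left out. Of the 272 tested probes, 20 have targets with runs of G, meaning at least 4 in a row or at least 2 runs of 3.

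Models were fitted with limma 3.58.1 and statmod 1.5.0 in R 4.3.3 over all 18 groups, with dye as a covariate, the array as a random block and empirical Bayes variances. The false discovery rate was set by the Benjamini-Hochberg method at 0.05 within each of 18 contrasts. Every adjusted p below is limma's. The contrasts were the stage change in each species and sex, D. simulans and D. yakuba against the mean of the 4 D. melanogaster strains in males at each stage, an F test among those 4 strains, males against females in Oregon-R and Zimbabwe-109 and in D. simulans, and the interactions of stage with sex and species. The p-values measure the spread between these replicates. Errors are standard errors of the fit. A probe below background in every sample of a group has only a bound there. Its fold is given as "at least", the bright group's mean against the dim group's mean of, per sample, the higher of the lowest detected signal and the probe's own signal. Folds of other dim probes are compressed by the offset. The number of arrays limits the precision.

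Before the data were examined, 11 lists of miRNAs, the contrasts, most alternatives and the rule for naming probes were fixed. By that rule, each contrast names up to 6 probes with the largest positive and up to 6 with the largest negative change at adjusted p under 0.05, with the same sign in every array (stage) or in every strain compared (species and sex). For the F tests it takes the 6 with the largest range of strain means and for interactions the 6 largest each way. Members of the fixed lists may be named as examples, and 1 probe per arm is named, the D. melanogaster probe first. Of the lists, 9 had at least 3 tested probes and were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. The early embryo cluster had 0 tested probes. The testis clusters had 2, too few for a set test.

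The fit was tested on simulated data with 20 probes changed at each of 3 sizes. For the stage change in D. melanogaster males it recovered 18, 20 and 20 of 20 probes changed by 0.5, 1 and 2 on the log2 scale, with 3 false calls among 212 unchanged. For D. simulans males it recovered 11, 18 and 20, with 1 false call. For D. simulans against D. melanogaster at the earlier stage the numbers were 11, 19 and 20, with 2 false calls. For sex in D. melanogaster at PF they were 13, 17 and 20, with 1, and for stage by sex 12, 17 and 20, with 1. The simulated values were drawn from the fitted spread, array correlation and dye effect, with no slide effect and most probes unchanged. The false calls therefore do not cover slide effects or comparisons in which most probes change.

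Alternatives covered the background correction, the normalization, the authors' table, the detection filter, the dye term, the block, the slide, the variance model, the samples in the fit and each array left out. Added after seeing the data were the authors' table centred on its median, the removal of probes with G runs, and fits restricted to probes listed for D. melanogaster or for both species compared. Duplex energies were computed with ViennaRNA 2.7.2; tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.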

Results

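The study asked how miRNA levels change at the onset of metamorphosis in Drosophila and how that differs between genotypes, species and sexes. Intensities of 1339 miRNA probes were compared in whole animals of 6 strains, at an earlier stage and at puparium formation (PF), in 48 male and 24 female samples. Between 87 and 278 probes were detected per sample, with a median of 163.5 in the male and 207.5 in the female samples. The brightest spot read 59687.2. All changes below are log2 differences ± SE from limma, and n counts arrays, each of which holds the 2 stages of a strain, sex and replicate. Levels of males and females were measured on separate slides.

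At puparium formation let-7, the miRNA that times developmental transitions in many animals, rose in every strain and in both sexes. In D. melanogaster males let-7 rose by 4.73 ± 0.12, or 26.6-fold (higher in 16 of 16 arrays, adjusted p = 1.28e-39). It was above background in 8 of the 16 earlier samples, so this fold rests partly on dim values. The same males also gained miR-279, known for its part in the formation of carbon dioxide sensing neurons (2.19 ± 0.11, 4.55-fold), and miR-2a of a family that targets pro-apoptotic genes (1.57 ± 0.10, 2.97-fold). The cluster partners of let-7 rose too: miR-100, above background in 0 of 16 earlier samples, at least 1.78-fold, and miR-125, above background in 1 of 16, by 1.32 ± 0.12 in 15 of 16 arrays. miR-34, linked to ageing of neurons, fell by 1.39 ± 0.09 in 16 of 16 arrays.

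In D. melanogaster males 184 of 272 tested probes changed, 127 up and 57 down, and 61 of the 90 probes listed for D. melanogaster were among them. The steepest falls were those of dme-mir-14-5p (-5.52 ± 0.26), aae-miR-92a* (-5.09 ± 0.37), dme-wu-mir-2318-5p (-5.05 ± 0.24), dsi-wu-mir-2329-5p (-4.82 ± 0.26), dme-mir-313-5p (-4.63 ± 0.18) and dsi-wu-mir-2208-3p (-3.89 ± 0.21), and all 6 have targets with runs of G. Further rises were those of bmo-miR-279a (2.09 ± 0.10), the custom probe sdylib-seq-1-3p (1.64 ± 0.11) and bmo-miR-2779 (1.54 ± 0.10). The split between up and down followed the scaling: 41 and 191 with median centring in place of loess, 98 and 79 in the authors' table, and 70 and 94 in that table once centred. The median of all probes was 0.13 and lay between -0.60 and 0.16 over 8 scalings.

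The miR-2 family rose as a group in D. melanogaster males, with 19 of 22 probes up and 0 down (19 up when adjusted over the list alone; camera adjusted p = 2.72e-04). The call was lost with adjusted p = 0.385 with an estimated correlation, and with 1 probe per arm (camera adjusted p = 0.0586). Its median of 0.80 stayed positive under all 8 scalings, from 0.24 to 1.23, although median centring left 10 up and 6 down. Among the probes of the ecdysone and heterochronic list, 17 of 34 rose and 8 fell (17 and 8 adjusted over the list alone; camera adjusted p = 0.856). In that list dme-miR-252 (0.75 ± 0.08) rose, while miR-34 and dme-mir-8-5p (-0.42 ± 0.08) fell. Of the gut, fat body and metabolism list 6 rose and 10 fell of 31 (6 and 9 adjusted over the list alone; camera adjusted p = 0.266). Among its members miR-305 (1.02 ± 0.10) and miR-275 (0.60 ± 0.07) rose, and miR-277, known to act on branched-chain amino acid breakdown, fell by 0.49 ± 0.10.

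Smaller groups were mixed in these males. The muscle list had 9 up and 1 down of 11 (9 and 1 adjusted over the list alone; camera adjusted p = 0.266). The 9 were all probes of miR-92, for example miR-92b (0.72 ± 0.10), known to act on the muscle factor Mef2, while miR-1, the main muscle miRNA, had 0.13 ± 0.12 (adjusted p = 0.342). The nervous system list had 12 up and 1 down of 21 (12 and 1 adjusted over the list alone; camera adjusted p = 0.856), among them miR-7 (0.72 ± 0.11) and miR-124 (0.16 ± 0.05). For the ovary list the counts were 4 up and 0 down of 7, for the Hox cluster 3 and 0 of 8, and for mirtrons 3 and 1 of 6. Each of these counts was the same adjusted over the list alone, and each camera adjusted p was 0.856. The direction of these groups depends on the scaling: over 8 scalings the nervous system list had 0 to 12 up and 1 to 19 down, with its median between -0.48 and 0.16, the ovary list 0 to 6 up and 0 to 6 down, the Hox cluster 0 to 3 up and 0 to 8 down and the mirtrons 1 to 4 up and 0 to 5 down. The ecdysone and heterochronic list likewise had 7 to 20 up and 8 to 20 down, and the gut, fat body and metabolism list 3 to 9 up and 9 to 26 down, with its median between -0.95 and -0.01.

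In D. melanogaster females let-7 rose by 5.09 ± 0.17 in 8 of 8 arrays (adjusted p = 1.32e-33). miR-100, above background in 1 of the 8 earlier samples, rose by 3.78 ± 0.13, or 13.7-fold as fitted. miR-125, not well above background in any of the 8 earlier samples, rose at least 8.92-fold. miR-1010, a mirtron released from its host intron by splicing, rose by 1.93 ± 0.14, miR-988 by 1.72 ± 0.12 and miR-279 by 1.68 ± 0.16. miR-34 fell by 2.05 ± 0.13. The steepest falls were again in dme-mir-14-5p (-6.94 ± 0.37), dsi-wu-mir-2329-5p (-6.76 ± 0.37), dme-wu-mir-2318-5p (-6.41 ± 0.34), aae-miR-92a* (-6.41 ± 0.52), dps-miR-2571* (-5.32 ± 0.46) and dme-mir-313-5p (-5.09 ± 0.25), each in 8 of 8 arrays.

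Altogether 207 of 272 probes changed in D. melanogaster females, 135 up and 72 down. The miR-2 family had 20 of 22 probes up and 0 down (20 adjusted over the list alone, camera adjusted p = 9.60e-04, and adjusted p = 0.561 with an estimated correlation), and its median of 1.16 stayed positive over the scalings, from 0.65 to 1.23. With 1 probe per arm the call was lost (camera adjusted p = 0.0602). In the gut, fat body and metabolism list 7 rose and 16 fell of 31 (7 and 16 adjusted over the list alone; camera adjusted p = 0.0837), with miR-305 at 1.03 ± 0.14 and miR-281 at -0.62 ± 0.15; over the scalings 4 to 8 rose and 12 to 20 fell. Under median centring 66 probes were up and 107 down, the authors' table had 97 of 203 calls up, and once centred it gave 91 and 89. Across the scalings the median of all probes, 0.19 in the fit reported, ranged from -0.19 to 0.36.

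In D. simulans the stage change ran along similar lines. let-7 rose by 4.93 ± 0.24 in males (30.4-fold) and by 4.68 ± 0.24 in females (25.6-fold), each in 4 of 4 arrays. miR-125 and miR-100, not well above background in any earlier sample, rose at least 2.64-fold and 3.29-fold in males and at least 11.6-fold and 6.35-fold in females. miR-276b rose by 2.25 ± 0.23 in males and 1.33 ± 0.23 in females. In males miR-2c (1.66 ± 0.28) and the custom probe dsi-wu-mir-2338-3p (2.18 ± 0.28) rose, while in females dpu-miR-252a (1.18 ± 0.24) and dpu-miR-252b (1.16 ± 0.26) did.

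The falls in D. simulans males were led by aae-miR-92a* (-6.54 ± 0.73), dme-mir-14-5p (-6.04 ± 0.52), dme-wu-mir-2318-5p (-5.24 ± 0.48), dme-mir-313-5p (-4.55 ± 0.36), dsi-wu-mir-2329-5p (-4.16 ± 0.52) and dsi-wu-mir-2208-3p (-3.15 ± 0.42). In females dme-mir-14-5p (-5.92 ± 0.52), dsi-wu-mir-2329-5p (-4.57 ± 0.52) and dsi-wu-mir-2338-5p (-2.71 ± 0.32) led. There aae-miR-92a*, dme-mir-313-5p and dsi-wu-mir-2359-3p were not well above background in any PF sample, and they fell at least 6.91-fold, 4.01-fold and 3.59-fold. In all, 122 probes changed in males, 88 up and 34 down, while in females 66 were up and 38 down. The miR-2 family had 15 of 22 up in males and 12 in females with 0 down (15 and 12 adjusted over the list alone; camera adjusted p = 2.53e-04 and 0.00846). Both calls were lost, at adjusted p = 0.401 and adjusted p = 0.552 with an estimated correlation, while both medians were positive under all 8 scalings. With 1 probe per arm both calls were lost too (camera adjusted p = 0.0857 and 0.251).

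The split in D. simulans males was 52 up and 32 down with plain background subtraction, 45 up of 149 with median centring, 66 and 46 in the authors' table and 65 and 40 in that table once centred. In females it was 37 and 36 with median centring and 51 and 48 in the authors' table. Over the scalings the median of all probes ranged from -0.53 to 0.16 in males and from -0.22 to 0.20 in females.

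In D. yakuba males let-7 rose by 5.39 ± 0.24, or 41.8-fold, in 4 of 4 arrays. miR-100 and miR-125 rose at least 4.99-fold and 4.25-fold, and miR-276b rose by 1.99 ± 0.23. The custom probes dsi-wu-mir-2338-3p (3.37 ± 0.28) and dsi-wu-mir-2338-5p (2.30 ± 0.32) rose too. Falls were led by aae-miR-92a* (-5.95 ± 0.73), dme-mir-14-5p (-4.76 ± 0.52), dme-wu-mir-2318-5p (-4.64 ± 0.49), dme-mir-313-5p (-4.05 ± 0.36), dsi-wu-mir-2329-5p (-2.78 ± 0.52) and dsi-wu-mir-2208-3p (-2.57 ± 0.42). Of 126 changed probes 84 were up and 42 down. The miR-2 family had 17 of 22 up and 0 down (18 adjusted over the list alone, camera adjusted p = 0.00107, and adjusted p = 0.662 with an estimated correlation), with a positive median under all 8 scalings. With 1 probe per arm its camera adjusted p was 0.0485. The nervous system list had 6 up and 7 down of 21 (6 and 8 adjusted over the list alone; camera adjusted p = 0.532), with miR-124 at 0.33 ± 0.09 and miR-137 at -0.42 ± 0.12, and over the scalings 1 to 6 up and 1 to 10 down. The split was 45 up and 49 down with median centring and 55 and 71 in the authors' table once centred, and the median of all probes ranged from -0.11 to 0.08.

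Taking the 9 strain and sex sets separately, which share no samples, 25 probes for 15 distinct arms or sequences were up in all of them and 18 probes for 12 were down. Forms of an arm from other species with another name and sequence, such as miR-279 and bmo-miR-279a, count separately here. Those down include dme-mir-14-5p, dme-mir-313-5p and aae-miR-92a*, whose targets have runs of G. let-7 ranged from 4.43 in Canton-S males to 5.39 in D. yakuba males. miR-276b (lowest 0.93), miR-279 (0.92), miR-2a (0.83), miR-2b (0.70), miR-2c (1.02), miR-125 (0.67) and miR-9a (0.61), the last known from sense organ precursors, were up in all 9. miR-34 lay between -1.12 and -2.50, and miR-958, dme-mir-284-5p, dme-mir-316-3p and miR-281-2* were also down in all 9. In Canton-S males miR-100 had only 0.31 ± 0.18 (adjusted p = 0.164), against 1.93 ± 0.18 in Oregon-R, 2.08 ± 0.18 in Samarkand and 1.39 ± 0.18 in Zimbabwe-109 males; these are fitted values from earlier samples of which 0 of 4 per strain were above background. Across the 272 probes, which are not independent replicates, the stage changes of 2 sets correlated at 0.682 to 0.948. With 4 arrays per set, males of Oregon-R, Canton-S, Samarkand and Zimbabwe-109 had 87, 128, 114 and 155 changed probes. D. simulans and D. yakuba males, with 122 and 126, lay within that range. Females of Oregon-R and Zimbabwe-109 had 183 and 172, more than D. simulans females with 66 up and 38 down.

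**Figure D1:**
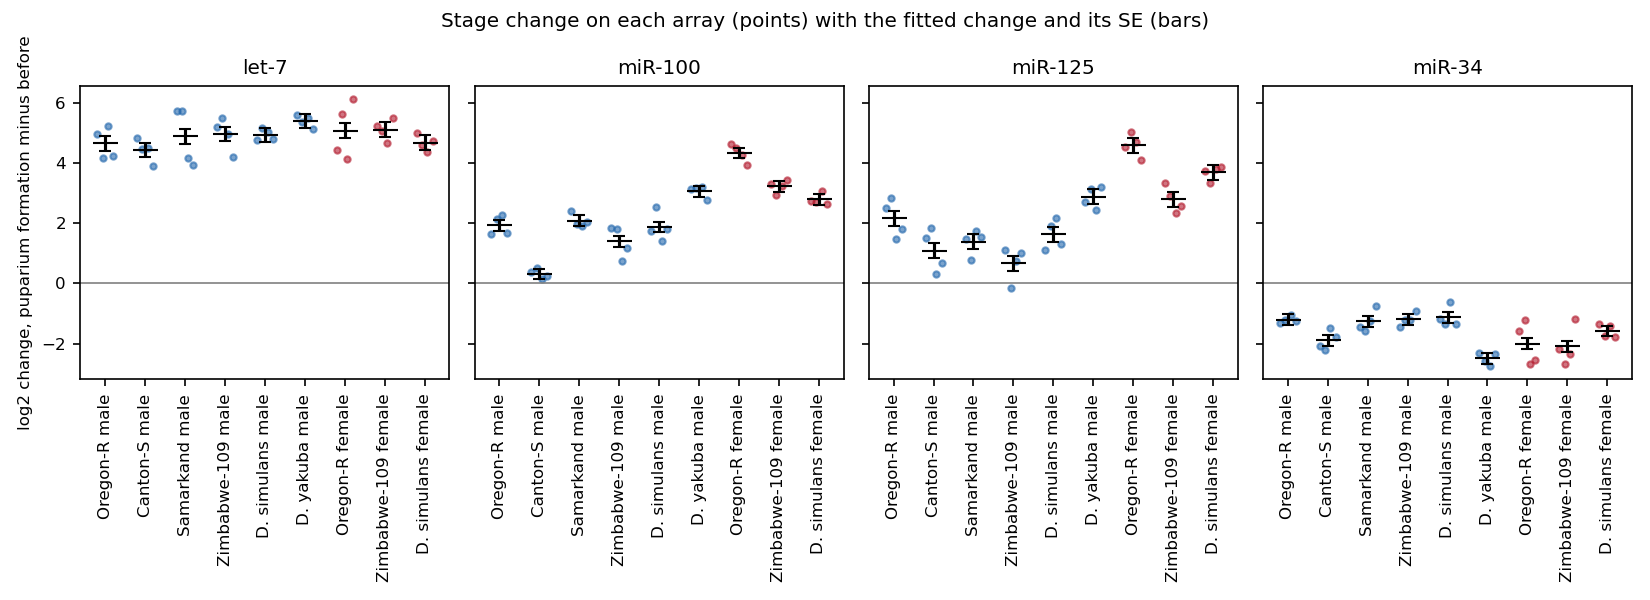
Stage change (PF minus earlier stage, log2) of let-7, miR-100, miR-125 and miR-34 on each array, for the 9 strain and sex sets. Blue points are male and red points female arrays, and black bars are the fitted value ± SE; let-7 sits between 4.43 and 5.39 in every set, while miR-100 reaches 4.33 in Oregon-R females and 0.31 in Canton-S males.

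Set against D. melanogaster males, D. simulans males had miR-2500 higher at both stages. The probe was detected in 4 of 4 D. simulans and 0 of 16 D. melanogaster samples at each stage, at least 3.02-fold higher early and at least 3.67-fold higher at PF (adjusted p = 8.20e-32 and 7.45e-32). dsi-miR-965 was at least 1.33-fold and 1.59-fold higher. dme-mir-305-3p was at least 2.90-fold lower early (adjusted p = 8.20e-12) and at least 3.30-fold lower at PF, while dsi-mir-305-3p, named for the other species, was higher at PF by 0.46 ± 0.16 (adjusted p = 0.0460). At PF sdylib-seq-1-3p was at least 6.57-fold lower and miR-289 4.01-fold lower (adjusted p = 1.23e-08). The sign was the same against each of the 4 strains, except for dme-mir-305-3p at PF, where it held against 3 of 4. Each other species is a single stock, so species and stock cannot be told apart, and a mismatch between a probe and the target of another species or strain was not tested.

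At the earlier stage 24 probes differed between D. simulans and D. melanogaster males, 13 higher and 11 lower in D. simulans. Higher were also aae-bantam-3p (0.80 ± 0.25), miR-13b (0.74 ± 0.24), dsi-wu-mir-2359-5p (0.71 ± 0.19) and dme-mir-996-5p (0.49 ± 0.16). Of these, miR-13b lost its call in 11 of 17 other settings, dme-mir-996-5p in 10 of 15, its sign turning in 1 of them, aae-bantam-3p in 7 of 14 and dsi-wu-mir-2359-5p in 5 of 14. Lower were miR-956 (-1.32 ± 0.24) and sdylib-seq-1-5p (-1.18 ± 0.21), and, with 0 of 4 D. simulans samples above background, sdylib-seq-1-3p (at least 1.93-fold), dme-mir-314-5p (at least 1.33-fold) and the custom probe 53-3p (at least 1.25-fold). At PF 32 differed, 21 higher and 11 lower. Those included miR-11 (0.78 ± 0.23), miR-278, known from energy balance (0.78 ± 0.20), miR-277 (0.75 ± 0.22) and dgr-miR-276b* (0.57 ± 0.20), against dme-miR-10-5p (-0.58 ± 0.16). With 0 of 4 D. simulans samples above background, the custom probe 53-3p was at least 1.78-fold, miR-956 at least 1.70-fold and sdylib-seq-1-5p at least 1.27-fold lower. The gut, fat body and metabolism list had 6 higher and 1 lower of 31 at PF (6 and 1 adjusted over the list alone; camera adjusted p = 0.771), and 0 to 6 higher over the scalings.

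With limma, 0 of the 50 tested probes listed for both species and 0 of the 60 detected in all samples were called at the earlier stage (9 and 12 at an unadjusted p under 0.05), and 4 of 50 and 3 of 60 at PF. Within the slide that held both, the sign of the early difference was kept by 22 of 24 probes against Oregon-R and 24 of 24 against Canton-S, and of the PF difference by 31 and 32 of 32; the probes were called from samples that include these, so the agreement is partly built in. On those slides miR-277 at PF was -0.03 against Oregon-R and 1.16 against Canton-S. With the slide as a fixed block, D. simulans was set against Oregon-R and Canton-S only, so the strains compared changed along with the slide term. There 32 probes differed early and 45 at PF. The calls of aae-bantam-3p and dme-mir-996-5p early and of miR-11, miR-278, miR-277 and dgr-miR-276b* at PF were lost. Whether the slide or the choice of strains cost these calls was not tested. dgr-miR-276b* lost its call in 10 of 14 other settings, miR-11 in 7 of 16 and miR-278 in 4 of 16. The early split was 2 higher and 27 lower with median centring, 7 and 10 with cyclic loess and 4 and 35 in the authors' table once centred. The PF split was 6 and 16, 14 and 19, and 4 and 13 in these settings, and 16 and 16 with quantile normalization. The median of all probes ranged from -0.45 to 0.03 early and from -0.27 to 0.04 at PF.

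D. yakuba males differed from D. melanogaster males in more probes. At the earlier stage miR-2c (1.33 ± 0.29), miR-263b, known to protect sensory bristles (1.32 ± 0.30), miR-92a (1.18 ± 0.27), cqu-miR-92 (1.08 ± 0.24), cqu-bantam* (0.97 ± 0.22) and miR-92b (0.89 ± 0.21) were higher. Not well above background in any D. yakuba sample were sdylib-seq-1-3p (at least 1.87-fold lower), t454m18-seq-6-5p (at least 1.89-fold), sdylib-seq-1-5p (at least 1.73-fold), the mirtron miR-1012 (at least 1.42-fold), dme-mir-314-5p (at least 1.29-fold) and the custom probe 53-3p (at least 1.21-fold). At PF the custom probe 153-5p was at least 1.61-fold higher, detected in 4 of 4 D. yakuba and 0 of 16 D. melanogaster samples, and miR-276b (1.22 ± 0.24), miR-100 (1.18 ± 0.19), miR-2c (1.14 ± 0.29), miR-125 (1.06 ± 0.26) and cqu-bantam* (0.88 ± 0.22) were higher. At least 8.96-fold, 4.33-fold and 2.40-fold lower were sdylib-seq-1-3p, miR-1012 and the custom probe 53-3p, and miR-986 (-1.42 ± 0.16), dme-wu-mir-2318-5p (-1.53 ± 0.50) and dme-mir-313-5p (-1.22 ± 0.37) were lower.

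For D. yakuba males the counts were 80 early, 51 higher and 29 lower, and 111 at PF, 68 higher and 43 lower. The miR-2 family had 10 higher and 0 lower of 22 early (10 adjusted over the list alone, camera adjusted p = 0.00394, and adjusted p = 0.425 with an estimated correlation), with a median of 0.53 that stayed between 0.29 and 1.48 over the scalings. With 1 probe per arm that call was lost (camera adjusted p = 0.458). The muscle list had 9 higher and 0 lower of 11 (9 adjusted over the list alone; camera adjusted p = 8.88e-05, and adjusted p = 0.425 with an estimated correlation). The 9 were all miR-92 probes, its median stayed positive in all 8 scalings, and miR-1 had 0.03 ± 0.24. The nervous system list had 6 higher and 0 lower of 21 (6 adjusted over the list alone; camera adjusted p = 0.0638), but over the scalings it had 3 to 12 higher and 0 to 10 lower, with its median between -0.74 and 0.76. Among 42 tested probes listed for both species 17 differed early and 18 at PF.

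Samarkand shared a slide with D. yakuba, and there 77 of 80 early and 107 of 111 PF differences, called from samples that include these, kept their sign. On that slide miR-100 and miR-2c at PF were only 0.41 and 0.30 above Samarkand, while miR-125 was 1.39 and miR-276b 1.055 above it. With the slide as a fixed block, D. yakuba was set against Samarkand and Zimbabwe-109 only, so the strains compared changed along with the slide term. There 51 probes differed early and 59 at PF. The early differences of miR-2c and miR-263b and the PF differences of miR-2c, cqu-bantam* and dme-mir-313-5p were no longer called. Whether the slide or the choice of strains cost these calls was not tested. At PF dme-mir-313-5p lost its call in 5 and dme-wu-mir-2318-5p in 4 of 14 other settings. The early split was 25 higher and 153 lower with median centring, 147 and 12 in the authors' table and 30 and 101 in that table once centred. At PF it was 161 and 6 in the authors' table and 28 and 89 in that table once centred. Across scalings the median of all probes ranged from -0.78 to 0.63 early and from -0.38 to 0.68 at PF.

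Among males of the 4 D. melanogaster strains, 101 probes differed at the earlier stage and 97 at PF by limma's F test. The largest ranges of strain means early were those of dme-wu-mir-2318-5p (7.16, adjusted p = 2.33e-13), dsi-wu-mir-2208-3p (7.06), bmo-miR-3366 (6.48), dps-miR-2571* (5.54), aae-miR-92a* (5.48) and dps-miR-1000* (5.29). Oregon-R was lowest in all 6, and Zimbabwe-109 was highest in 5 of them. The targets of dme-wu-mir-2318-5p, dsi-wu-mir-2208-3p and aae-miR-92a* have runs of G, that of dps-miR-2571* does not. At PF dsi-wu-mir-2338-5p (6.05) and dsi-wu-mir-2338-3p (6.01, adjusted p = 4.72e-20) had the largest ranges, from the 4 Oregon-R to the 4 Zimbabwe-109 males, followed by dsi-wu-mir-2329-5p (4.38). bmo-miR-2774c (3.41) was highest in Oregon-R, and dme-mir-14-5p (2.96) and dsi-wu-mir-2359-3p (2.93) were lowest there. The targets of dsi-wu-mir-2329-5p and dme-mir-14-5p have runs of G. What RNA dsi-wu-mir-2338-5p and dsi-wu-mir-2338-3p report was not tested. Where a strain lies below background, its range is a fitted value, as for dsi-wu-mir-2338-3p with 0 of 4 Oregon-R males detected. With the slide as a fixed block, the F test covered only Oregon-R against Canton-S and Samarkand against Zimbabwe-109. There 66 probes differed early and 55 at PF, and the PF calls of dme-mir-14-5p and dsi-wu-mir-2359-3p were lost. Without replicate 3 of the Oregon-R males, 64 probes differed at PF.

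Between the sexes of D. melanogaster, females had more miR-375 and miR-263b than males at both stages. miR-375 was lower in males by -2.43 ± 0.43 early and -2.21 ± 0.43 at PF, and miR-263b by -1.86 ± 0.27 early and -1.65 ± 0.27 at PF. The dim probe for miR-14, known from ecdysone signalling and fat metabolism, was at least 3.22-fold and 3.05-fold lower in males, detected in 0 of 8 male and in 5 and 6 of 8 female samples. That holds for the probe with the D. melanogaster sequence only, since a probe for the mosquito form, aae-miR-14, had 0.00 ± 0.15 and 0.04 ± 0.15, and with only the groups compared in the fit the miR-14 calls were lost (adjusted p = 0.0892 and 0.0571). At PF miR-988 (-1.80 ± 0.16), miR-1010 (-1.68 ± 0.18), bmo-miR-279b (-3.10 ± 0.47) and tca-miR-13a (-1.87 ± 0.28) were also lower in males.

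Higher in D. melanogaster males early were dme-mir-313-5p (1.58 ± 0.33), ame-miR-928 (1.10 ± 0.20), cqu-miR-92 (1.06 ± 0.22), miR-100 (0.87 ± 0.17) and miR-92b (0.82 ± 0.19), and miR-125 was at least 1.30-fold higher. Both miR-100 and miR-125 were near background at that stage, detected in 1 of 16 samples each, for miR-100 a female one. Neither difference is therefore a measured one. miR-100, cqu-miR-92 and miR-92b turned sign under another scaling. Lower early were dps-miR-2550* (-2.16 ± 0.50), dps-miR-2571* (-1.80 ± 0.60) and bmo-miR-279b (at least 1.87-fold). At PF the custom probes dsi-wu-mir-2338-3p (3.44 ± 0.26, 10.9-fold) and dsi-wu-mir-2338-5p (3.27 ± 0.29) led the probes higher in males. For both of these probes the 4 of 8 male samples above background at PF were all of Zimbabwe-109, with 0 of 4 in Oregon-R. The male mean thus averages a strain with signal in males and a strain without. What RNA these 2 custom probes report was not tested. Next came dsi-wu-mir-2359-3p (at least 3.23-fold), dme-mir-313-5p (1.66 ± 0.33), dsi-wu-mir-2208-3p (at least 2.20-fold) and dme-wu-mir-2318-5p (1.42 ± 0.45).

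The sexes of D. melanogaster differed in 99 probes early, 46 higher and 53 lower in males, and in 142 at PF, 55 higher and 87 lower. The miR-310 cluster, a fast-evolving relative of miR-92, had 6 of 9 probes higher in males and 0 lower at each stage (6 adjusted over the list alone; camera adjusted p = 0.0112 and 0.00490). Those calls were lost, at adjusted p = 0.422 and adjusted p = 0.276 with an estimated correlation, while the medians were positive under all 8 scalings. With 1 probe per arm they were lost too (adjusted p = 0.0717 and 0.0554). miR-311 (at least 1.34-fold and 1.70-fold) and miR-312 (at least 1.26-fold and 1.54-fold), not above background in any female sample, are examples. The muscle list had 6 higher and 0 lower of 11 early (7 and 1 adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.771 with an estimated correlation). These were all miR-92 probes, and their list's median went from -0.57 to 0.78 over the scalings, negative in the authors' table. The ovary list had 0 higher and 4 lower of 7 at PF (0 and 4 adjusted over the list alone; camera adjusted p = 0.164), with miR-79 at -1.03 ± 0.13, and over the scalings 0 to 2 higher and 3 to 7 lower. Of the testis clusters miR-964 was at least 2.18-fold higher in males at PF (adjusted p = 0.0151) and miR-974 was at -0.02 ± 0.07 (adjusted p = 0.833).

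No slide held both sexes, so slide and sex cannot be told apart. With the slide as a random block in place of the array, 58 probes differed early in D. melanogaster and 95 at PF. In that setting the calls of miR-125 and dps-miR-2571* early and of dme-wu-mir-2318-5p and dsi-wu-mir-2208-3p at PF were lost. The early split was 99 higher and 28 lower with median centring, 67 and 48 with cyclic loess, 9 and 195 in the authors' table and 76 and 38 in that table once centred. At PF it was 35 and 91 with plain background subtraction, 63 and 52 with median centring, 8 and 175 in the authors' table and 75 and 51 in that table once centred. Depending on the scaling, the median of all probes ranged from -0.76 to 0.32 early and from -0.68 to 0.20 at PF.

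In D. simulans the sexes differed in 44 probes early, 16 higher and 28 lower in males, and in 41 at PF, 17 higher and 24 lower. miR-263b was lower in males at both stages (-1.61 ± 0.38 and -1.42 ± 0.38), as was dpu-miR-252a (-1.90 ± 0.31 and -1.77 ± 0.31). At PF miR-125 (-2.19 ± 0.33, 4.57-fold), miR-988 (-1.24 ± 0.22), miR-1010 (-1.07 ± 0.26) and miR-100 (-0.96 ± 0.24) were lower in males. dsi-wu-mir-2338-3p (4.84 ± 0.37, 28.7-fold), dsi-wu-mir-2338-5p (4.51 ± 0.41), miR-305 (1.53 ± 0.25), dsi-wu-mir-2359-5p (at least 2.02-fold), dsi-wu-mir-2359-3p (at least 1.60-fold) and miR-312 (at least 1.23-fold) were higher, the call of dsi-wu-mir-2359-3p being lost in 5 of 14 other settings and without 7 of 8 arrays. miR-375 did not pass the test in this species (-0.21 ± 0.60 and 0.05 ± 0.60, adjusted p = 0.865 and 0.962).

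Early in D. simulans let-7 was lower in males (-1.0 ± 0.32, adjusted p = 0.0207), as were miR-276b (-0.90 ± 0.30), der-miR-10 (-0.87 ± 0.29) and miR-306 (-0.85 ± 0.24). They lost their call in 6, 9, 9 and 5 of 15 other settings and without 4, 6, 5 and 1 of 8 arrays. Higher were aae-miR-92a* (3.63 ± 0.96), dme-wu-mir-2318-5p (3.33 ± 0.63), dme-mir-313-5p (2.61 ± 0.46), dsi-wu-mir-2208-3p (2.46 ± 0.54), dme-mir-14-5p (1.94 ± 0.68) and bmo-miR-2783 (1.79 ± 0.35), all with runs of G; dme-mir-14-5p lost its call in 6 of 14 other settings and without 6 of 8 arrays. The miR-310 cluster again had 6 of 9 higher and 0 lower at each stage (6 adjusted over the list alone; camera adjusted p = 1.55e-12 and 3.38e-08). These are the 2 list calls of 15 that held with an estimated correlation (adjusted p = 8.3e-05 and adjusted p = 0.00275 with an estimated correlation), and both medians were positive under all 8 scalings. With 1 probe per arm the early call was kept (adjusted p = 0.00103) and the PF call was lost (adjusted p = 0.0525). The ecdysone and heterochronic list had 0 higher and 7 lower of 34 at PF (1 and 7 adjusted over the list alone; camera adjusted p = 0.0309, and adjusted p = 0.103 with an estimated correlation), and over the scalings 0 to 1 higher and 4 to 10 lower.

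With the slide as a random block in place of the array, 26 probes differed early and 23 at PF between the sexes of D. simulans. Many named calls were lost: those of miR-263b at both stages, of let-7, miR-276b, der-miR-10, miR-306 and dme-mir-14-5p early, and of miR-1010 and dsi-wu-mir-2359-3p at PF. No slide held both sexes, so the calls that remained are not cleared of a slide effect. The early split was 15 higher and 11 lower with plain background subtraction, 17 and 2 with median centring, 14 and 15 with cyclic loess, 12 and 10 in the authors' table and 19 and 4 in that table once centred. At PF it was 14 and 10 with median centring and 13 and 10 in the authors' table once centred. The median of all probes ranged from -0.14 to 0.50 early and from -0.03 to 0.22 at PF.

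**Figure D2:**
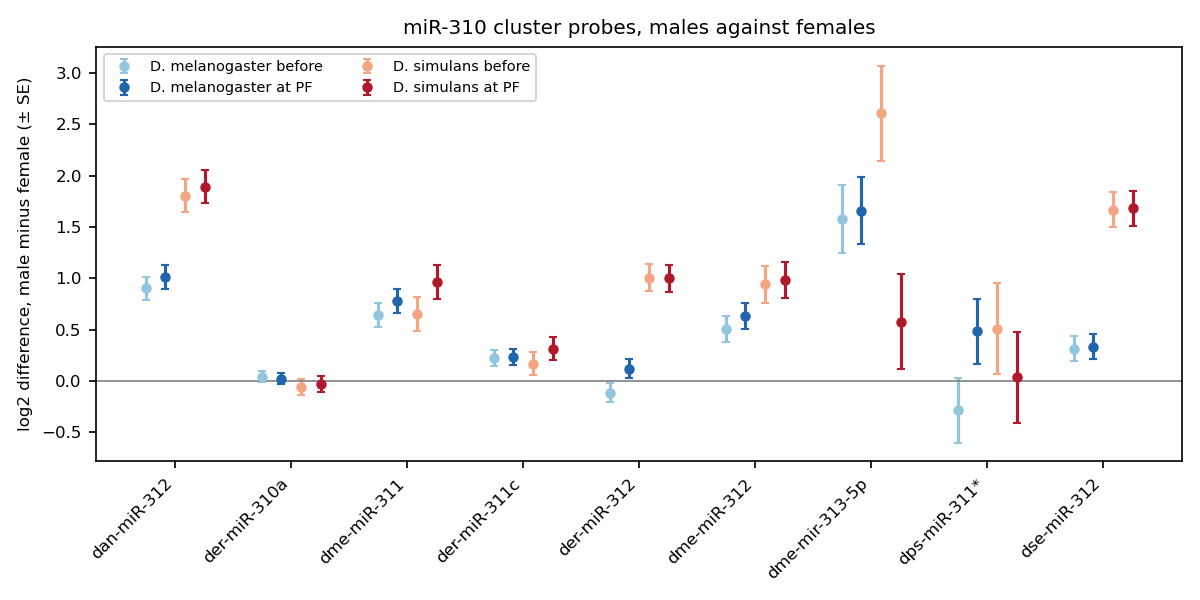
Male minus female difference (log2 ± SE) of the 9 tested probes of the miR-310 cluster in D. melanogaster and D. simulans at each stage. In each of the 4 comparisons 6 of the 9 probes are called higher in males and 0 lower, and the median stays positive under all 8 scalings. The 9 include forms of the same arm from other species and dme-mir-313-5p, whose target has runs of G.

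The stage change itself differed between the sexes in 48 probes over the 3 strains with females, 20 with a positive and 28 with a negative difference, taken as the signed male change minus the female change. miR-125 (-2.20 ± 0.20) and miR-100 (-1.72 ± 0.15) rose less in males, as did miR-988 (-1.23 ± 0.14) and miR-1010 (-1.14 ± 0.16), while let-7 had -0.11 ± 0.20 (adjusted p = 0.788). For miR-125 and miR-100 the earlier samples were almost all below background, so these differences are fitted values; at PF itself they were lower in D. melanogaster males by -1.37 ± 0.23 and -1.25 ± 0.17. ame-miR-928 (-1.10 ± 0.17) and bmo-miR-279b (-1.14 ± 0.41) also had negative differences. dsi-wu-mir-2338-5p (3.36 ± 0.26) and dsi-wu-mir-2338-3p (3.31 ± 0.23) had the largest positive difference, followed by dps-miR-2550* (2.03 ± 0.44), dps-miR-2571* (1.72 ± 0.53), miR-964 (1.36 ± 0.44) and dps-miR-375* (1.08 ± 0.36). dps-miR-2550*, dps-miR-375* and ame-miR-928 were above background in 0 of 4 PF samples of every group, so their values rest on the early samples, with no measured PF level. The gut, fat body and metabolism list had 4 probes with a higher change in males and 0 lower of 31, all 4 of miR-281 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0430, and adjusted p = 0.690 with an estimated correlation), and 0 to 7 higher over the scalings. Without replicate 4 of the Zimbabwe-109 females 75 probes differed, and miR-964, dps-miR-375*, dps-miR-2571* and bmo-miR-279b lost their call in 9 of 15, 8 of 14, 7 of 15 and 6 of 15 other settings and without 2, 5, 2 and 16 of 24 arrays. The split was 5 and 23 with plain background subtraction, 3 and 18 with median centring, 22 and 20 in the authors' table and 8 and 18 in that table once centred, and the median of all probes ranged from -0.20 to 0.07.

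Between D. simulans and D. melanogaster males the stage change differed in 3 of 272 probes, all with a negative difference, the signed change in D. simulans minus that in D. melanogaster. They were sdylib-seq-1-3p (-1.62 ± 0.24), miR-289 (-1.57 ± 0.28) and dsi-mir-314-5p (-0.54 ± 0.08), the last named after its value was seen. sdylib-seq-1-3p was above background in 0 of 4 D. simulans males at each stage, and dsi-mir-314-5p in 0 of 16 D. melanogaster males at each stage, so no stage change was measured on that side and both values are fitted ones. The Hox cluster list had 0 probes called of 8, with 31 of all 272 at an unadjusted p under 0.05, and 5 lower adjusted over the list alone, such as dme-miR-10-3p (-0.53 ± 0.20). Its camera adjusted p was 0.00120, and adjusted p = 0.0807 with an estimated correlation. Leaving out replicate 2 of Canton-S or replicate 3 of Zimbabwe-109 gave 6 and 10 probes, and leaving out D. simulans replicate 1 or 3 gave 5 and 6. The split was 1 higher and 3 lower with no background correction, 3 and 5 with quantile normalization, 2 and 5 in the authors' table and 6 and 2 in that table once centred, and the median of all probes ranged from 0.00 to 0.23.

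In D. yakuba males the stage change differed from that of D. melanogaster males in 54 probes, 24 with a higher and 30 with a lower change. miR-100 (1.64 ± 0.20) and miR-125 (1.55 ± 0.28) rose more in D. yakuba, and dsi-wu-mir-2338-3p (2.17 ± 0.31), dsi-wu-mir-2329-5p (2.04 ± 0.58), dsi-wu-mir-2338-5p (1.82 ± 0.35) and bmo-miR-3366 (1.62 ± 0.50) also had higher changes. miR-34 (-1.11 ± 0.20), dme-mir-34-3p (-1.14 ± 0.29), sdylib-seq-1-3p (-1.62 ± 0.24), miR-1012 (-1.09 ± 0.29), miR-277 (-0.75 ± 0.23) and miR-275 (-0.68 ± 0.16) had lower ones. sdylib-seq-1-3p and miR-1012 were above background in 0 of 4 D. yakuba males at each stage and bmo-miR-3366 in 0 of 4 PF samples of every group, so their values are fitted ones with no measured stage change in D. yakuba. For miR-100 and miR-125 the earlier samples were almost all below background, so their differences in change are fitted values too. At PF itself both were higher in D. yakuba, as given above. The nervous system list had 2 higher and 8 lower of 21 (3 and 9 adjusted over the list alone; camera adjusted p = 0.353), among them miR-263a (-0.62 ± 0.17); over the scalings it had 0 to 2 higher and 0 to 8 lower, with its median between -0.35 and 0.47. Without D. yakuba replicate 4, 26 probes differed. Calls were lost for miR-277 in 8 of 16 other settings, miR-275 in 5 of 17, bmo-miR-3366 in 5 of 15, dme-mir-34-3p in 4 of 16, miR-34 and miR-1012 in 3 of 16, dsi-wu-mir-2329-5p in 3 of 15, and miR-125 and sdylib-seq-1-3p in 1 each. The split was 14 and 1 with plain background subtraction, 61 and 1 with median centring, 19 and 9 with cyclic loess, 27 and 9 in the authors' table and 17 and 8 in that table once centred, and the median of all probes ranged from -0.08 to 0.62.

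**Figure D3:**
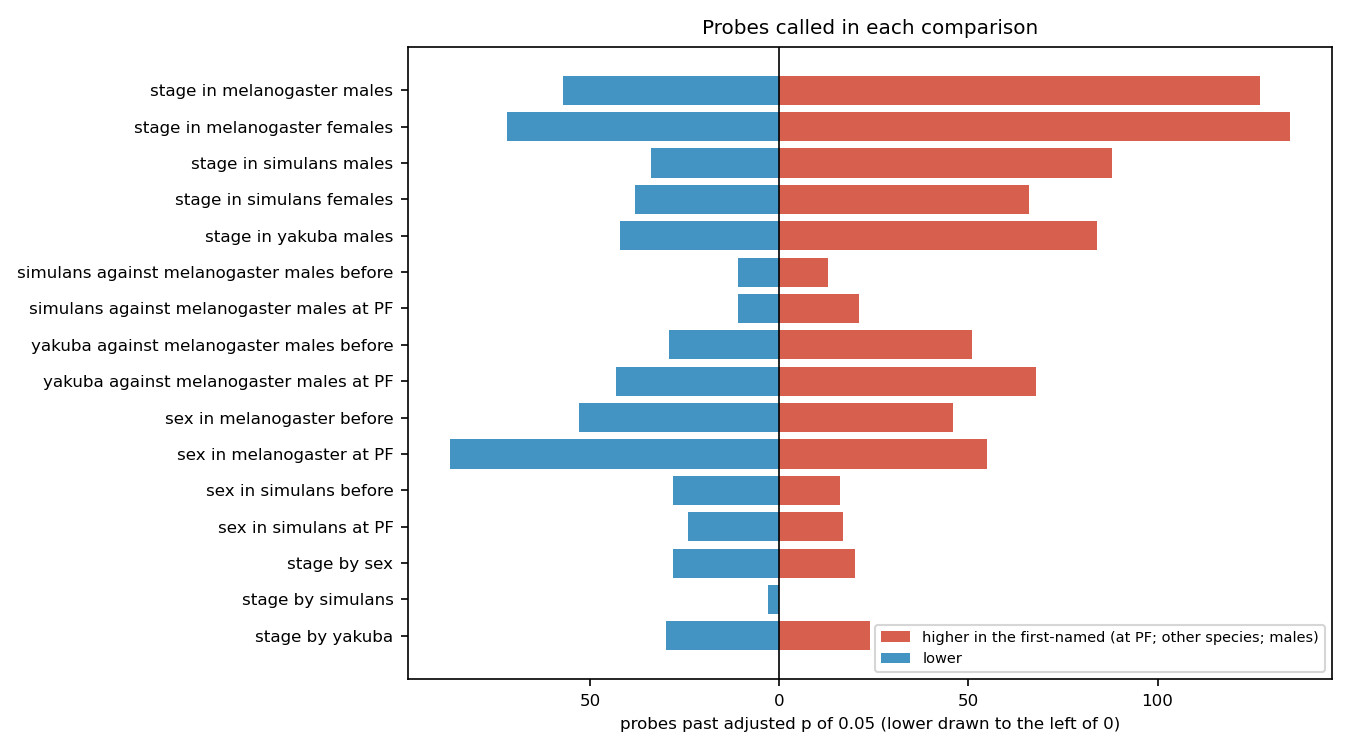
Number of the 272 tested probes called higher (right) and lower (left) in each of 16 comparisons at adjusted p under 0.05. The stage changes of D. melanogaster call the most, 184 in males and 207 in females, and stage by D. simulans the fewest, with 3. The D. melanogaster stage changes rest on 16 male and 8 female arrays, those of the other species on 4 each. These counts therefore do not compare the species at an equal number of arrays.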

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

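Chosen only after the result was seen were the regroupings that part every pair and 6 tests: the scaling and the runs of G for the falling probes, the slope in Zimbabwe-109 and D. simulans with the scaling and the slides for miR-100 and miR-125, and the scaling for dsi-wu-mir-2338-5p and dsi-wu-mir-2338-3p.

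At puparium formation (PF), 14 probes fell over 4-fold in D. melanogaster males, and among their 12 distinct targets 9 have runs of G. G runs stand in 75% of these targets and in 3.50% of the others, with a Fisher exact p of 5.48e-10 over 269 distinct targets, so a signal tied to G runs is possibly part of the fall. The median change nearest to 0 over 8 scalings was -3.64, against -4.26 as reported. This test could hardly end otherwise, since the probes were picked for a fall of over 4-fold. The scalings moved the median of all probes only between -0.60 and 0.16, so no conclusion on the scaling is drawn from it. Whether the G-run probes carry 1 shared signal cannot be told: their deviations correlate at a median of 0.287, above the 95th percentile of random sets, 0.134, but under the bound set in advance. dme-mir-14-5p fell by 5.52 in these males while aae-miR-14, a probe for the other arm, was at -0.14 (adjusted p = 0.149).

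miR-125 and miR-100 differed between the sexes in their stage change, by -2.20 and -1.72 in males against females, the interaction test being what marked them. In Oregon-R the male changes of other probes had a slope of 0.475 on the female ones, so compression on the male arrays may account for part of it there, although let-7 had a male to female ratio of 0.917 on the same arrays. In Zimbabwe-109 and D. simulans the slope exceeded the male to female ratio of miR-125 by at least 0.429. Compression of the size seen over the other probes thus falls short of it there. A stronger compression near background is not excluded, since the earlier levels of miR-125 and miR-100 were mostly below background. The test did not cover miR-100, whose ratios were 0.432 and 0.671 against slopes of 0.902 ± 0.0436 and 0.871 ± 0.0737. The errors of the slopes treat the probes as independent. Both differences stayed negative and past the threshold under all 8 scalings, so none of these removes them. Their size depended on the scaling. With quantile normalization they were -1.29 for miR-125 and -0.70 for miR-100, the difference nearest to 0. With 0 slides holding both sexes, slide and sex cannot be separated.

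dsi-wu-mir-2338-5p and dsi-wu-mir-2338-3p had the largest positive difference in stage change between the sexes (3.36 and 3.31) and differed in D. yakuba (1.82 and 2.17), again by the interaction tests. The predicted duplex of the 2 targets, -12.5 kcal/mol, is weaker than the weakest of 30 known pairs of arms, -13.9, so that arms of a hairpin are not what the prediction gives. Their deviations correlate at 0.804 across 72 samples (permutation p = 1.0e-05, the smallest possible), barely over the bound set in advance, but at 0.774 without the 2 farthest samples, under it, so whether the 2 signals have 1 source is left open. The male excess at PF was at least 2.17 in both species over 8 scalings, so none of these scalings accounts for it. What RNA the 2 probes report, and whether it comes from the flies, was not tested, so their sex and species values are those of a signal of unknown origin.

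The stage change also differed between the sexes, by the interaction test, for dps-miR-2550* (2.03), dps-miR-2571* (1.72), miR-964 (1.36), dps-miR-375* (1.08), miR-988 (-1.23), bmo-miR-279b (-1.14), miR-1010 (-1.14) and ame-miR-928 (-1.10). Between D. simulans and D. melanogaster males the fitted values differed for sdylib-seq-1-3p (-1.62), above background in 0 of 4 D. simulans males at each stage, and miR-289 (-1.57). D. yakuba males differed in dsi-wu-mir-2329-5p (2.04), miR-100 (1.64), bmo-miR-3366 (1.62), miR-125 (1.55), sdylib-seq-1-3p (-1.62), dme-mir-34-3p (-1.14), miR-34 (-1.11), miR-1012 (-1.09), miR-277 (-0.75) and miR-275 (-0.68), of which sdylib-seq-1-3p and miR-1012 were above background in 0 of 4 D. yakuba males at each stage. The earlier levels of miR-100 and miR-125 were almost all below background, so their values, like that of bmo-miR-3366, are fitted ones.

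Of 90 groups tested for a sample far from the others, 3 had such a sample, and chance alone gives about 1 in 20. In D. simulans females at PF, replicate 4 had 147 probes detected against 182 to 185 in the others. In D. simulans males at PF, replicate 3 had 201 against 162 to 164. In Oregon-R males at PF, miR-125 read 7.09 in replicate 4 against 8.71 to 8.98. Outside the miRNA probes, 6 of 8 probes for 2S rRNA were above background in all 72 samples, and the others in at least 61.

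Samples were also regrouped at random, with the real grouping counted. For the stage changes most regroupings break the pairs on the arrays, and only 1 grouping, the real one, called as many probes, the highest other being 192 in D. melanogaster females, 70 and 52 in D. simulans males and females and 72 in D. yakuba males. Among 100 regroupings of D. melanogaster that part every pair, added after the result was seen, 1 called as many, 184 against 150 in males and 207 against 186 in females, so chance is excluded there. In D. simulans and D. yakuba only 8 regroupings part every pair, too few for a share under 0.05, with 58, 28 and 30 as the highest others in D. simulans males, its females and D. yakuba males. For D. simulans at PF (32 against 12) and D. yakuba early (80 against 42) and at PF (111 against 28), and for stage by D. yakuba (54 against 11), the real grouping alone reached its count, but the regroupings ignore strain, and whole strains give too few groupings for a share under 0.05. The real grouping alone reached its count for the strains early (101 against 58) and at PF (97 against 28). It also did so for sex in D. melanogaster at PF (142 against 81) and sex in D. simulans (44 against 6 and 41 against 7). For sex in D. melanogaster early and stage by sex, 2 groupings of 100 reached the count (99 against 101 and 48 against 52). For the strains, sex and stage by sex, the share of such groupings lay under 0.05. Chance among single samples, or single arrays for stage by sex, is therefore unlikely. It is not excluded for sex in D. melanogaster early and stage by sex, where another regrouping called more probes than the real one. The regroupings ignore the slide, which parts the sexes fully and the strains mostly, so an effect of the slide is not excluded. For D. simulans early and stage by D. simulans, 5 of 100 did, so chance is not excluded for these counts (24 against 36 and 3 against 19, the latter, in a single regrouping, several times the real count, which points to a structure of the samples that was not tested).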

How the results depend on the processing

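Of 194 named results, 129 kept their direction and their side of the threshold in every setting that tested them, arrays left out aside. Only 15 were tested among probes detected in all samples and 12 among probes listed for both species. With the array as a fixed block 86 were tested. Of 2728 values of named results with an array left out, 2620 stayed the same and 108 lost their call. Without background correction 192 stayed the same, without the dye term 190, and with the trend and robust variance 193; no count moved by over 1.5 times in these settings, nor with the array as a fixed replicate block. The authors' table centred on its median, the fits without G-run probes, those on D. melanogaster probes and those on probes listed for both species were chosen after seeing the data. Where no reason is given below, the cause was not tested.

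Plain background subtraction gave 63 probes for stage in D. simulans females, 58 for the strains at PF, 26 for sex in D. simulans early, 28 for stage by sex and 15 for stage by D. yakuba. Median centring gave 178 and 48 for D. yakuba early and at PF, 154 and 39 for the strains, 19 and 24 for sex in D. simulans and 21 for stage by sex. Quantile normalization gave 66 for D. yakuba at PF and 8 for stage by D. simulans, and cyclic loess 29 for sex in D. simulans early and 28 for stage by D. yakuba. The authors' table gave 15 and 17 for D. simulans, 159 and 167 for D. yakuba, 57 for the strains at PF, 204 for sex in D. melanogaster early, 22 and 18 for sex in D. simulans and 7 for stage by D. simulans. Once centred, it gave 39 and 17 for D. simulans, 131 for D. yakuba early, 46 for the strains at PF, 23 and 23 for sex in D. simulans, 26 for stage by sex, 8 for stage by D. simulans and 25 for stage by D. yakuba.

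With no detection filter, 1339 probes were tested, and sex in D. melanogaster had 225 and 263, sex in D. simulans at PF 63 and stage by D. yakuba 33. Fewer probes are tested when only the 60 detected in all samples are kept. These gave 45 and 37 for stage in D. melanogaster males and females, 30 and 28 in D. simulans and 30 in D. yakuba. For D. simulans they gave 0 with limma (12 at an unadjusted p under 0.05) and 3, for D. yakuba 12 and 26, for the strains 28 and 22, for sex in D. melanogaster 19 and 31 and in D. simulans 5 and 3. Stage by sex and stage by D. simulans had 0 with limma (11 and 11 unadjusted) and stage by D. yakuba 22. The 90 D. melanogaster probes, again fewer, gave 61, 70, 42, 37 and 47 for the stage changes in the same order, 8 and 12 for D. simulans, 29 and 42 for D. yakuba, 34 and 34 for the strains, 31 and 54 for sex in D. melanogaster, 10 and 9 in D. simulans, and 14, 5 and 18 for stage by sex, D. simulans and D. yakuba. Of probes listed for both species, D. simulans had 0 of 50 with limma (9 unadjusted) and 4, and D. yakuba 17 and 18 of 42. Without the G-run probes, 252 were tested and stage by D. simulans had 5.

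Without the replicate block, stage in D. simulans females had 67 probes, stage by sex 28 and stage by D. yakuba 27. With the slide as a fixed block, D. yakuba had 51 and 59, the strains 66 and 55 and stage by D. simulans 6. For the levels of species and strains this setting also compared fewer strains with each other, as given above. As a random block in place of the array it left 58 for sex in D. melanogaster early and 26 and 23 in D. simulans, where slide and sex cannot be told apart. Fits of only the groups compared, which hold fewer samples, gave 159 for stage in D. simulans females, 51 for D. simulans at PF, 45 for sex in D. melanogaster early, 75 and 82 in D. simulans and 10 for stage by D. simulans.

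Reversed early were dme-mir-996-5p in D. simulans (-0.0480, median centring) and, for sex in D. melanogaster, miR-100 (-0.0666 with quantile normalization, -0.12 in the authors' table), cqu-miR-92 (-0.30) and miR-92b (-0.41), both in that table. With each array left out in turn, the strains at PF had 64 probes (without Oregon-R male 3) to 98 (without Zimbabwe-109 male 3), stage by sex 37 (without Oregon-R female 2) to 75 (without Zimbabwe-109 female 4), stage by D. simulans 3 to 10 (without Zimbabwe-109 male 3) and stage by D. yakuba 26 (without D. yakuba male 4) to 62 (without Oregon-R male 3). Of 144 list tests, 15 were called with the preset correlation, 2 with an estimated correlation and 3 with 1 probe per arm. Signal over background limits the dim probes, with 87 to 278 of 1339 detected per sample.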

Other observations

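Probes made for the sequence of a species and its sister differed from each other, a pair chosen after its values were seen. dme-mir-305-3p was above background in 0 of 4 Samarkand males at PF and averaged at least 8.57 in the other 3 D. melanogaster strains (adjusted p = 1.79e-14 for the strains), and in D. simulans males it was detected in 0 of 4 samples at each stage. In D. yakuba males at PF it was at 0.23 ± 0.21 relative to D. melanogaster (adjusted p = 0.407). dme-mir-314-5p was at least 1.33-fold lower in D. simulans early while dsi-mir-314-5p, above background in 3 of 4 D. simulans and 0 of 16 D. melanogaster males, was higher (adjusted p = 1.52e-16).

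Among the D. melanogaster strains before PF, miR-279 ranged from 9.36 in Zimbabwe-109 to 12.85 in Oregon-R males, a probe named after its values were seen. At PF miR-100 was lowest in Canton-S (6.42) and highest in Samarkand (8.65), and miR-125 ranged from 7.09 in Zimbabwe-109 to 8.39 in Oregon-R.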
